A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

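The series holds 4 Affymetrix Yeast Genome S98 arrays of Saccharomyces cerevisiae, 2 of strains with Snf1-I132G and 2 of strains with wild-type Snf1. Total RNA was prepared by glass bead lysis, treated with DNase, column-purified, copied into biotin-labelled cRNA with an Enzo kit and hybridized, per the labels' protocols. Per the series' design text, RNA combined from 3 transformants of each strain was run in duplicate. Nothing in the labels says that the duplicates came from separate cultures, so no p-value here can be taken to measure the spread between cultures. Those of single genes measure only the spread between these arrays, which may be technical. The list tests with a preset correlation and the permutation tests, described below, set genes or probe sets against others. Their p-values do not measure replication across arrays.

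The deposited values are array signal intensities on a linear scale made with MAS5, per the submitters' processing notes. The MAS5 version is not given in the sources used here, and its detection calls were not used here. The values show that each array had been scaled, since the mean after trimming 2% from each end was 500 to 501 on all 4 arrays. Such scaling fixes the average of each array, so a change of most transcripts in one direction would be spread over the others. Probe sets were named through the platform annotation. Of 9275 non-control probe sets 6504 had 1 gene, 328 had several and 2443 had none given, and only those with 1 gene were named. All 6504 matched the RefSeq gene table of assembly R64, with 0 symbols changed. That table was used for names, RNA classes and gene lengths only. The build behind the array design is not given in the sources used here, so no coordinates are reported.

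Signals were taken as log2(value + 16), and folds are on this scale, which understates the change of dim genes. A gene whose 2 arrays of one group both lie below the 25th percentile of their array has a fold that rests on this pseudocount. The 60 control probe sets were left out of the tests. Probe sets were kept if their mean over the 4 arrays reached the 25th percentile of the non-control probe sets, which left 6956. Of these 5720 had 1 gene and stood for 5202 genes. The groups were compared with limma 3.58.1 (lmFit and eBayes with an intensity trend, no covariates) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 3.63, and the median standard error was 0.193 log2 units. With the pair as a block 1 residual degree of freedom remains. All adjusted p-values of single genes come from limma's moderated test.

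A gene with several probe sets was taken at the one with the highest mean. Of 249 genes with several tested probe sets 80 had unequal calls, among them NOP58. Of these, 3 had probe sets called in opposite directions, namely TOM1, TOR1 and YPK9, which were singled out after their values were seen.

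The 40 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The named genes were the 12 with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, up to 4 members with the smallest p of each list described, and SNF1, SNF4, GCN4, SUC2, ADH2, HXT1, INO1, URA3, LEU2, HIS3, TRP1, LYS2 and ADE2. Other genes are named where they are the few exceptions of a list or complete its calls, and were chosen after their values were seen. Lists were tested with limma's camera at a preset correlation of 0.01 on 1 probe set per named gene, with Benjamini-Hochberg adjustment over the 39 lists that had at least 3 tested members. The list of early sporulation genes had 1 of its 8 members past the filter and was not tested. Camera with an estimated correlation, camera on ranks and fry were run as alternatives. Counts adjusted over the list alone use the members of 1 list at a time.

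The same-numbered arrays of the 2 groups were treated as pairs. The file labels in the sample descriptions share a string between the groups for replicate 1 and another for replicate 2. This was read as the mark of a shared run, a reading that is not certain. The deviations of same-numbered arrays from their group means also correlated, at r = 0.515 across probe sets. The pair was entered as a block in an alternative fit, and differences within each pair were computed.

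The other alternatives were quantile normalization, centring each array on its median, pseudocounts of 1 and 64, no filter and a filter at the 50th percentile, eBayes without the trend and with robust estimation, 1 probe set per named gene, and leaving out each array in turn. Leaving out an array leaves 1 in its group, which is then assumed to vary like the other group. Centring on the 9 hybridization control probe sets, and keeping only probe sets whose name ends in a plain _at, were added after seeing the data.

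The fit was tested on simulated data for the comparison of Snf1-I132G and Snf1 over 6956 probe sets, with 100 changed by 1 log2 unit and 100 by 2. It recovered 70% of the former and 99% of the latter, with 17 false calls among 186 and 0 of the wrong sign. With no simulated change it called 0. The set test was checked on 5202 simulated genes and 39 lists. It called 0 lists without a shift, and it called the 1 list shifted by 0.5 log2 units and 0 others. Simulated noise was drawn independently for each gene and array. Neither check could therefore show how correlation between genes, or between the arrays of a pair, affects the tests. Permutation tests were two-sided with 1e+05 draws, and brightness-matched comparisons used 10000 random lists drawn within 10 bins of mean signal. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.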

Results

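Transcript levels were measured in budding yeast carrying either wild-type Snf1 or the Snf1-I132G form. Snf1 is the yeast AMP-activated protein kinase, needed for growth on carbon sources other than glucose. The Snf1-I132G form is sensitive to the pyrazolopyrimidine 2NM-PP1, an inhibitor designed to act on that form and not on wild-type Snf1. Both strains were moved from 2% glucose to 2% raffinose with 0.05% glucose for 120 min and were then given 25 µM 2NM-PP1 for 40 min. Each group had 2 Affymetrix Yeast Genome S98 arrays, made from RNA combined from 3 transformants. All 4 arrays came from cells with the inhibitor, so an effect of the I132G allele itself was not separated from inhibition of the kinase. Differences are given as Snf1-I132G minus Snf1, so that a positive value is higher where the kinase was open to inhibition.

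Of the 9335 probe sets in the table, 60 were controls and 6956 of the others passed the brightness filter. The median signal was 131 and 139 on the Snf1-I132G arrays and 151 and 161 on the Snf1 arrays. Across probe sets, the log2 signals of the Snf1-I132G arrays correlated with each other at r = 0.976 and those of the Snf1 arrays at r = 0.981. Between the groups r was 0.900 to 0.920. Probe sets are not independent replicates, and the 2 arrays of a group limit the precision of every value.

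The comparison addressed which transcripts are held down, and which are kept up, by active Snf1 in cells short of glucose. Gcn4 targets, cytosolic ribosomal protein genes and every tested list of amino acid synthesis but that of serine and glycine were higher in Snf1-I132G, while glucose-repressed Snf1-dependent genes and those of oxidative phosphorylation, peroxisomal beta-oxidation and storage carbohydrate were lower (camera with a preset correlation). With an estimated correlation no list passed (camera, lowest adjusted p = 0.198), and 6 did at an unadjusted p under 0.05. ARG1, which encodes argininosuccinate synthetase, had the largest rise on the scale used, log2(signal + 16), to a signal of 5525 ± 22.2 (SD, n = 2) from 281 ± 60.3, a log2 difference of 4.24 ± 0.19 (SE). RGI2, a gene of energy metabolism under respiratory growth, had the largest fall on that scale, to 253 ± 197 from 5791 ± 1334, a log2 difference of -4.64 ± 0.53. Under the alternatives only the named genes were ranked. Among them RGI2 lost that rank to SFC1 with a pseudocount of 1, at -4.75 against -4.97. It also lost the rank to PCK1 without replicate 1 of Snf1-I132G, and to HXT5 without replicate 2 of Snf1-I132G or replicate 1 of Snf1. Within pair 2 alone PHO84 was at 4.55 and ARG1 at 4.44, and PCK1 was at -4.31 and RGI2 at -4.05. At a Benjamini-Hochberg adjusted p under 0.05 in limma, 709 probe sets were higher and 1212 were lower in Snf1-I132G, which is 27.6% of those tested. Taken once per named gene, 470 genes were higher and 1036 were lower.

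The same-numbered arrays formed 2 pairs that each held both groups. At least 2-fold higher in both pairs were 318 probe sets, against 30.1 if the pairs were independent, and 486 were at least 2-fold lower in both, against 69.6. No probe set was 2-fold changed in opposite directions. The log2 differences of the 2 pairs correlated at Pearson r = 0.881 and Spearman rho = 0.858 across probe sets. Both pairs may hold the same RNA pools, in which case such agreement shows only that the measurement repeats. The excess over independent pairs therefore says nothing of replication across cultures. With the pair as a block, 1354 probe sets were higher and 1984 lower, and these included all 1921 called without it. Leaving out replicate 1 of Snf1 left 326 higher and 509 lower, and leaving out replicate 2 of Snf1 left 325 and 451.

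The split between rises and falls depended on the scaling of the arrays. The median log2 difference over all tested probe sets was -0.10 on the deposited scale, 0.03 after quantile normalization, 0.09 after median centring and -0.31 after centring on hybridization controls. Rises were 36.9% of the called probe sets on the deposited scale. Quantile normalization gave 829 higher and 913 lower, or 47.6% rises, and median centring gave 960 higher and 815 lower, or 54.1%. Centring on hybridization controls, chosen after seeing the data, gave 490 higher and 2055 lower, or 19.3%.

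**Figure D1:**
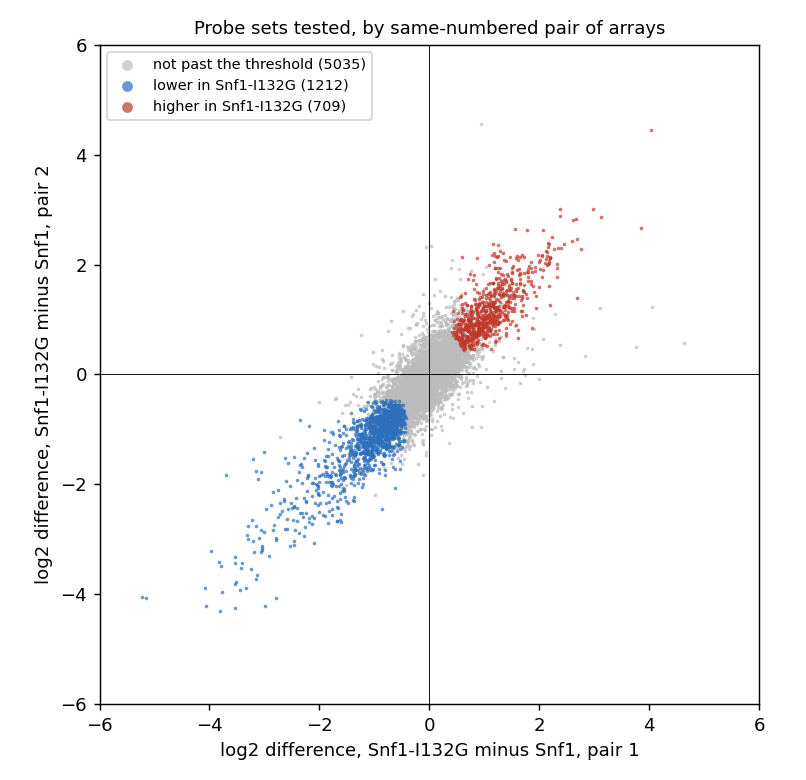
Log2 difference of each tested probe set, Snf1-I132G minus Snf1, in pair 1 (x axis) against pair 2 (y axis); each point is a probe set, in red for the 709 higher, blue for the 1212 lower and grey for those not past the threshold. The differences of the 2 pairs lie along a common diagonal (r = 0.881 across probe sets).

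Among the largest rises on that scale, ARG1 was followed by TPO2, a polyamine exporter gene, at a log2 difference of 3.25 ± 0.34. The TPO2 probe set does not have a plain _at name. STR3, encoding a cystathionine beta-lyase, rose by 2.99 ± 0.28. ARG3, for ornithine carbamoyltransferase, rose by 2.99 ± 0.17, and as its signal in Snf1 was 30.0 ± 1.2 (SD, n = 2), that size rests partly on the pseudocount. ORT1, the mitochondrial ornithine transporter gene, rose by 2.75 ± 0.18 and HIS1, the first enzyme of histidine synthesis, by 2.71 ± 0.15. HXT1, a low-affinity glucose transporter gene, rose by 2.69 ± 0.20, from 362 ± 69.8 to 2411 ± 293. The mitochondrial carrier gene YMC2 followed at 2.64 ± 0.22, then MET17 at 2.52 ± 0.50, HIS4 at 2.52 ± 0.15, HOM3 at 2.41 ± 0.20 and SAM1 at 2.37 ± 0.23. Limma's adjusted p was 0.018 for MET17 and at most 0.0039 for the other 11.

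Among the largest falls was that of HXT5, a hexose transporter gene of slow-growing cells, at -4.61 ± 0.72, with Snf1-I132G arrays at 66.0 and 342 and a Snf1 mean of 4428. SFC1, the mitochondrial succinate-fumarate transporter gene, was at -4.14 ± 0.25 and PCK1, for the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, at -4.06 ± 0.19. The isomaltase gene IMA5 was at -3.99 ± 0.18, the Hsp70 gene SSA3 at -3.89 ± 0.50, the peroxisomal thiolase gene POT1 at -3.87 ± 0.19 and IDP2, for cytosolic isocitrate dehydrogenase, at -3.68 ± 0.21. YMR206W, TMA10, ISF1 and YNL194C were at -3.68 ± 0.17, -3.65 ± 0.15, -3.64 ± 0.19 and -3.62 ± 0.22. SFC1 and IMA5 had signals of 17.8 and 29.1 in Snf1-I132G, so their sizes rest partly on the pseudocount. The adjusted p from limma was 0.0096 for HXT5, 0.0060 for SSA3, 0.0049 for RGI2 and at most 0.0016 for the others.

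**Figure D2:**
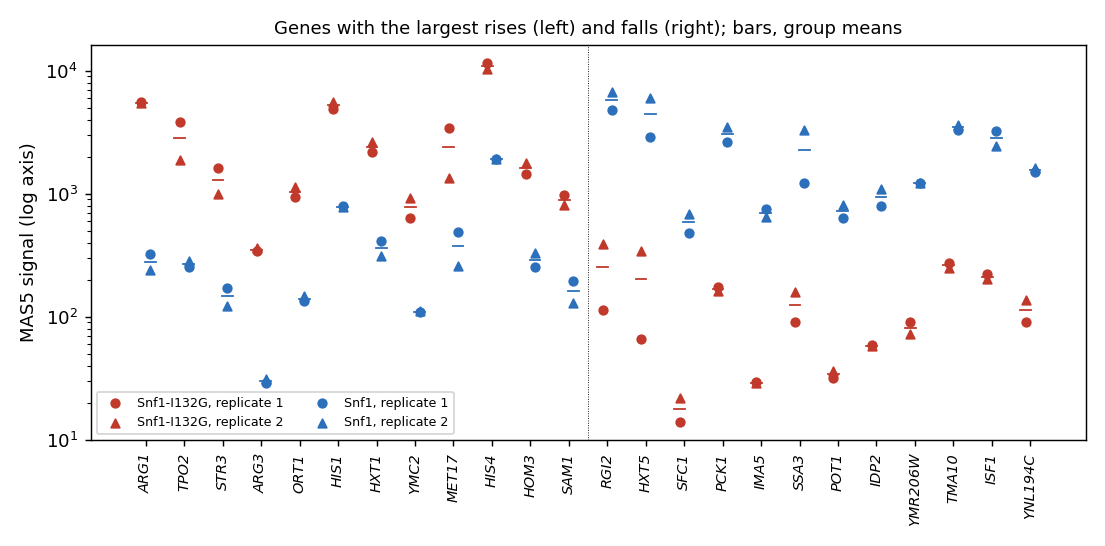
Deposited MAS5 signal on a log axis for the 12 named genes with the largest rises (left) and the 12 with the largest falls (right); points are single arrays, red for Snf1-I132G and blue for Snf1, circles for replicate 1 and triangles for replicate 2, and bars are group means. For each of these genes both arrays of one group lie above both of the other, from 5525 against 281 on average for ARG1 to 253 against 5791 for RGI2.

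The kinase gene itself had similar signals in both groups, 843 ± 65.3 in Snf1-I132G and 998 ± 23.9 in Snf1 (SD, n = 2). Its log2 difference of -0.24 ± 0.15 did not pass (limma, adjusted p = 0.28). The I132G change alters the protein, so this level is no check of the labels. SNF4, the gamma subunit gene, differed by -0.48 ± 0.17 (limma, adjusted p = 0.091, or 0.024 with the pair as a block). In the list of Snf1 complex and regulator genes 2 of 15 fell and 13 did not pass, with the same 2 falls when adjusted over the list alone (camera, adjusted p = 0.18; median -0.34). Those 2 were the activator genes CAT8 at -3.47 ± 0.17 and ADR1 at -2.17 ± 0.18, and CAT8 was at a signal of 11 in Snf1-I132G, so its size rests partly on the pseudocount. With the block 6 fell and 1 rose, and with centring on hybridization controls 8 fell. MIG1, the glucose repressor gene, differed by -1.42 ± 0.42 (limma, adjusted p = 0.056, or 4.1e-04 with the block), and SIP2, a beta subunit gene, by -0.79 ± 0.23 (0.055, or 0.011).

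Textbook targets that need Snf1 for expression without glucose were lower. Among 27 tested glucose-repressed Snf1-dependent genes 26 fell, also 26 when adjusted over the list alone, with a median log2 difference of -2.07 (camera, adjusted p = 2.4e-09; adjusted p = 0.198 with an estimated correlation). The median was -2.07 in pair 1 and -1.78 in pair 2. SUC2, the invertase gene, fell from 3334 ± 343 to 421 ± 93.4, by 2.95 ± 0.20, on a probe set that more than 1 transcript can match. ADH2, the glucose-repressed alcohol dehydrogenase gene, fell from 1365 ± 551 to 249 ± 105, by 2.38 ± 0.38 (limma, adjusted p = 0.010). ALD4, a mitochondrial aldehyde dehydrogenase gene, fell by 2.93 ± 0.17. The exception was SIP4, an activator gene, at 0.78 ± 0.27 (limma, adjusted p = 0.087) with a dim Snf1 signal of 26.6, and it rose when adjusted over the list alone, with the pair as a block (adjusted p = 0.012), with median centring and without replicate 1 of Snf1-I132G. Leaving out replicate 2 of Snf1 left 17 falls.

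Every gene of the glucose-repressed list is also in at least 1 of 3 regulon lists, so these lists largely count the same genes again. Only ICL2, MTH1, GAL1, GAL3 and GAL4 are in a regulon list and not in the glucose-repressed list. Most tested genes of the 3 lists were lower. Of the Cat8-dependent genes 13 of 14 fell, with a median of -2.17 (camera, adjusted p = 1.9e-05; adjusted p = 0.303 with an estimated correlation). Adjusted over the list alone 13 fell and 1, SIP4, rose, as it also did with the block, with median centring and without replicate 1 of Snf1-I132G. FBP1, for fructose-1,6-bisphosphatase, fell by 3.60 ± 0.38 to a signal of 31.1. Of the Adr1-dependent genes 9 of 10 fell, and 9 adjusted over the list alone, at a median of -1.57 (camera, adjusted p = 1.4e-04; adjusted p = 0.198 with an estimated correlation). Among them the acetate transporter gene ADY2 was at -2.54 ± 0.38 and SPS19 at -1.48 ± 0.23, and ICL2 at -0.68 ± 0.33 did not pass, though it did with the pair as a block (limma, adjusted p = 0.027). Of the Mig1-repressed sugar genes 8 of 10 fell, or 9 adjusted over the list alone, at a median of -1.32 (camera, adjusted p = 4.1e-04; adjusted p = 0.198 with an estimated correlation). The hexokinase gene HXK1 was at -1.98 ± 0.15, MTH1 at -2.62 ± 0.27 and HXT4 at -1.53 ± 0.18, while GAL3 at -0.57 ± 0.18 and GAL1 at 0.09 ± 0.19 did not pass, though GAL3 did with the block (limma, adjusted p = 0.028). Mig1-repressed falls numbered 5 without replicate 1 of Snf1 and 5 without replicate 2 of Snf1, and Adr1-dependent falls 5 without replicate 2 of Snf1.

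Hexose transporter genes moved both ways. Of 10 tested transporter and sensor genes 2 rose and 7 fell, with the same counts adjusted over the list alone, and the list as a whole did not shift (camera, adjusted p = 0.14; median -1.61). HXT1 rose, and so did HXT3, another low-affinity transporter gene, at 1.29 ± 0.15. Among the falls were HXT8 at -1.81 ± 0.17, whose signal of 29.0 in Snf1-I132G makes that size rest partly on the pseudocount, SNF3, for a glucose sensor, at -1.82 ± 0.20, and HXT2, for a higher-affinity transporter, at -3.10 ± 0.38. HXT6 and HXT7 fell, at -1.25 ± 0.23 and -1.68 ± 0.20, on probe sets that near-identical genes share. RGT2 at 0.25 ± 0.20 did not pass. HXT2, HXT3, HXT6, HXT7 and RGT2 were named after their values were seen.

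Respiratory genes were lower. Of 32 genes of oxidative phosphorylation 30 fell, and all 32 when adjusted over the list alone, at a median of -1.15 (camera, adjusted p = 8.1e-11; adjusted p = 0.198 with an estimated correlation). NDE1, for the external NADH dehydrogenase, fell by 2.42 ± 0.16, and COX4, ATP16 and COR1 were at -1.61 ± 0.14, -1.39 ± 0.14 and -1.39 ± 0.15. The 2 that did not pass were ATP5 at -0.92 ± 0.28 and CYC1 at -1.07 ± 0.43, and with the block they did (limma, adjusted p = 0.0011 and 0.0067). In the TCA cycle 14 of 15 genes fell, and 15 adjusted over the list alone, at a median of -1.36 (camera, adjusted p = 2.35e-07; adjusted p = 0.301 with an estimated correlation). The aconitase gene ACO1 was at -3.11 ± 0.28, the succinate dehydrogenase genes SDH1 and SDH2 at -2.90 ± 0.18 and -1.84 ± 0.15 and LSC2 at -2.43 ± 0.20, and LSC1 at -0.58 ± 0.18 did not pass, though it did with the block (limma, adjusted p = 0.0041). Of the peroxisomal beta-oxidation genes 10 of 12 fell, or 11 adjusted over the list alone, at a median of -1.22 (camera, adjusted p = 1.8e-04; adjusted p = 0.266 with an estimated correlation). ECI1 was at -2.10 ± 0.23, a size that rests partly on the pseudocount as its signal was 21.5 in Snf1-I132G, MDH3 at -1.30 ± 0.16 and PEX11 at -1.03 ± 0.16, and FAT1 and PXA2 did not pass, though FAT1 did with the block (limma, adjusted p = 0.011). Leaving out replicate 1 of Snf1 left 19 falls in oxidative phosphorylation and 6 in beta-oxidation, and leaving out replicate 2 of Snf1 left 19 and 5.

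Storage carbohydrate and stress genes were lower as well. Of 16 storage carbohydrate genes 13 fell, or 14 adjusted over the list alone, at a median of -1.53 (camera, adjusted p = 7.0e-06; adjusted p = 0.237 with an estimated correlation). GAC1, for a phosphatase subunit of glycogen control, was at -3.11 ± 0.17, GLC3, the glycogen branching enzyme gene, at -2.71 ± 0.22, GDB1 at -2.34 ± 0.18 and ATH1 at -1.72 ± 0.17. UGP1, NTH1 and TPS3 did not pass, though UGP1 did with the block (limma, adjusted p = 2.8e-04). Of 15 Msn2/Msn4 stress genes 10 fell, also 10 adjusted over the list alone, at a median of -1.46 (camera, adjusted p = 1.8e-04; adjusted p = 0.198 with an estimated correlation). XBP1, SOD2, TFS1 and the catalase gene CTT1 were at -2.52 ± 0.19, -2.44 ± 0.18, -2.03 ± 0.19 and -1.46 ± 0.16. GPD1, HSP12, SPI1, ALD3 and YGP1 did not pass, though GPD1 did with the block (limma, adjusted p = 0.0022). Of 17 heat-shock chaperone genes 10 fell, or 11 adjusted over the list alone, at a median of -0.91 (camera, adjusted p = 4.1e-04; adjusted p = 0.304 with an estimated correlation). SSA4 was at -2.06 ± 0.15, HSP104 at -1.71 ± 0.20 and HSP42 at -1.31 ± 0.18, and without replicate 2 of Snf1 the list had 6 falls.

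Inositol and phospholipid genes were lower, led by INO1, for inositol-3-phosphate synthase. INO1 fell from a signal of 406 ± 90.0 to 24.0 ± 2.8 (SD, n = 2), a log2 difference of -3.39 ± 0.22 that rests partly on the pseudocount. Of the 13 genes of the list 8 fell, also 8 adjusted over the list alone, at a median of -0.79 (camera, adjusted p = 8.4e-04; adjusted p = 0.198 with an estimated correlation). The phosphatidylcholine pathway genes OPI3, CHO1 and CHO2 were at -1.23 ± 0.16, -1.12 ± 0.16 and -1.05 ± 0.15, and CKI1, PSD1, FAS2, OPI1 and PIS1 did not pass. With the block the list had 12 falls, the exception being PIS1, and with centring on hybridization controls it also had 12. Falls numbered 5 without replicate 1 of Snf1 and 4 without replicate 2 of Snf1.

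Targets of Gcn4, the transcriptional activator of amino acid synthesis genes, were higher. Of 49 tested targets 41 rose and none fell, and 43 rose when adjusted over the list alone, at a median of 1.53 (camera, adjusted p = 4.8e-28; adjusted p = 0.198 with an estimated correlation). The median was 1.50 in pair 1 and 1.62 in pair 2. This list was chosen with knowledge that the study had named Gcn4, so its direction is not independent evidence. GCN4 itself had a signal of 8204 ± 22.3 in Snf1-I132G and 6476 ± 455 in Snf1, a log2 difference of 0.34 ± 0.15 (limma, adjusted p = 0.16, or 0.045 with the pair as a block). Among 12 genes of the Gcn4 pathway and the eIF2 and eIF2B translation factors none rose and 1 fell, with the same counts adjusted over the list alone. That gene was GCN2, the eIF2 kinase gene, at -0.80 ± 0.17 (limma, adjusted p = 0.023), and it no longer passed under median centring, nor without replicate 1 of Snf1, replicate 2 of Snf1 or replicate 2 of Snf1-I132G. GCN3 and GCD7, for subunits of eIF2B, were at 0.76 ± 0.22 (limma, adjusted p = 0.052, or 0.0027 with the block) and 0.60 ± 0.20 (0.081, or 0.018). Rises in that list numbered 3 with the block, 2 with median centring and 1 each with quantile normalization, with a filter at the 50th percentile, with 1 probe set per named gene, with plain _at probe sets and without replicate 1 of Snf1-I132G. The pathway list's shift, at a median of 0.28, passed (camera, adjusted p = 0.044; adjusted p = 0.362 with an estimated correlation). It was lost under quantile normalization (camera, adjusted p = 0.054), with centring on hybridization controls (0.10), and without replicate 1 of Snf1 (0.091), replicate 2 of Snf1 (0.061) or replicate 2 of Snf1-I132G (0.11).

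Most genes of the arginine, histidine, lysine and threonine pathways rose, and most of them are also in the Gcn4 list. In arginine synthesis 7 of 8 tested genes rose, at a median of 1.98 (camera, adjusted p = 1.1e-08), with ARG7 at 2.19 ± 0.15 and ARG8 at 0.61 ± 0.20, which did not pass, though it did with the pair as a block (limma, adjusted p = 0.016). In histidine synthesis all 6 tested genes rose, at a median of 1.84 (camera, adjusted p = 5.0e-07), among them HIS5 at 2.07 ± 0.15 and HIS7 at 1.62 ± 0.18. In lysine synthesis 6 of 8 rose, at a median of 1.39 (camera, adjusted p = 7.5e-07), led by LYS20 at 2.18 ± 0.17, LYS1 at 2.05 ± 0.18 and LYS2 at 1.89 ± 0.15, while LYS9 and LYS5 did not pass, though LYS9 did with the block (limma, adjusted p = 0.015). In aspartate-family and threonine synthesis 6 of 8 rose, at a median of 1.54 (camera, adjusted p = 7.4e-07), with HOM2 at 2.02 ± 0.18, THR1 at 1.65 ± 0.15 and THR4 at 1.42 ± 0.14, while HOM6 and AAT2 did not pass, though HOM6 did with the block (limma, adjusted p = 0.035). Adjusted over the list alone, the rises were 8 in arginine, 6 in histidine, 7 in lysine and 6 in threonine synthesis. With an estimated correlation, adjusted p = 0.198 for the arginine, histidine and threonine lists and adjusted p = 0.237 for lysine.

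Aromatic amino acid synthesis had 11 of 13 genes higher, or 12 adjusted over the list alone, at a median of 1.50 (camera, adjusted p = 1.1e-08; adjusted p = 0.198 with an estimated correlation). ARO4, ARO2, ARO1 and TRP2 rose by 1.96 ± 0.17, 1.75 ± 0.16, 1.65 ± 0.16 and 1.51 ± 0.14. PHA2 at 0.50 ± 0.18 and ARO9 at -0.67 ± 0.40 did not pass, and with the pair as a block both did (limma, adjusted p = 0.048 and 0.021). Without replicate 2 of Snf1-I132G 1 aromatic gene fell. In branched-chain synthesis 9 of 11 genes rose, or 10 adjusted over the list alone, at a median of 1.17 (camera, adjusted p = 2.5e-07; adjusted p = 0.198 with an estimated correlation). LEU9 rose by 2.12 ± 0.17, BAT1 by 1.58 ± 0.20, ILV3 by 1.43 ± 0.18 and ILV1 by 1.17 ± 0.17, while LEU1 and BAT2 did not pass, though LEU1 did with the block (limma, adjusted p = 0.0011). Of 21 sulfur assimilation and methionine genes 8 rose and 1, the S-methylmethionine permease gene MMP1, fell, at a median of 0.54 (camera, adjusted p = 2.2e-05; adjusted p = 0.222 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell. MET22 rose by 2.16 ± 0.18. Sulfur gene rises numbered 5 without replicate 1 of Snf1 and 5 without replicate 2 of Snf1, and MMP1 no longer passed without replicate 2 of either strain.

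Serine and glycine genes did not shift as a list (camera, adjusted p = 0.28). Their median was -0.08 and their mean 0.07, with the test's direction upward, and the median turned to 0.08 under quantile normalization and 0.10 under median centring. SER2 at 1.04 ± 0.25 and SER1 at 0.57 ± 0.16 rose among the 9 genes, and none did when adjusted over the list alone. Neither rise held without replicate 1 of Snf1 or without either array of Snf1-I132G, and SER1, at an adjusted p of 0.0495 in limma, was also lost without replicate 2 of Snf1, with a pseudocount of 1, without the brightness filter, without the intensity trend, with robust estimation and with centring on hybridization controls. GCV3 and GCV1, of the glycine cleavage system, were at -0.49 ± 0.33 and -0.38 ± 0.35 and did not pass, and GCV3 fell with the pair as a block (limma, adjusted p = 0.024).

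Aminoacyl-tRNA synthetase genes rose in 12 of 18 cases, or 16 adjusted over the list alone, at a median of 0.81 (camera, adjusted p = 4.9e-09; adjusted p = 0.198 with an estimated correlation). ILS1, for the isoleucyl enzyme, rose by 1.83 ± 0.14, DED81 by 1.26 ± 0.17, WRS1 by 1.22 ± 0.15 and THS1 by 1.20 ± 0.16. Rises numbered 6 without replicate 1 of Snf1. Of 11 purine genes 3 rose, ADE12 by 1.01 ± 0.17, ADE3 by 0.81 ± 0.18 and ADE13 by 0.60 ± 0.17, and adjusted over the list alone 6 rose and 1 fell (camera, adjusted p = 0.0021; median 0.46; adjusted p = 0.378 with an estimated correlation). ADE6 was at 0.59 ± 0.17 (limma, adjusted p = 0.053, or 0.0075 with the block). ADE13 no longer passed without the brightness filter or without the intensity trend. With the block 7 purine genes rose and 1 fell, with median centring 6 rose and with centring on hybridization controls 1 rose and 1 fell. Leaving out either Snf1 array left no purine rise, and leaving out either Snf1-I132G array left 1, while the list's shift was lost without replicate 2 of Snf1 (camera, adjusted p = 0.053). Of 8 pyrimidine genes 4 rose, also 4 adjusted over the list alone, at a median of 0.78 (camera, adjusted p = 0.0089; adjusted p = 0.343 with an estimated correlation). These were URA3, URA2 at 0.99 ± 0.18, URA6 at 0.90 ± 0.23 and URA5 at 0.77 ± 0.15. Pyrimidine rises numbered 2 without replicate 1 of Snf1, 1 without replicate 2 of Snf1, 2 without replicate 2 of Snf1-I132G and 2 with centring on hybridization controls, where 1 gene fell. With the block 5 pyrimidine genes rose and 1, URA1 at -0.45 ± 0.16, fell (limma, adjusted p = 0.014, or 0.090 without the block).

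The tested laboratory marker genes, each of them also in a list above, were higher as a list. Of 6 tested 5 rose, or 6 adjusted over the list alone, at a median of 1.66 (camera, adjusted p = 7.0e-06; adjusted p = 0.222 with an estimated correlation). The cells grew in medium without uracil, and URA3 rose from 1174 ± 48.8 to 3193 ± 28.6 (SD, n = 2), by 1.43 ± 0.14. LEU2 rose by 1.35 ± 0.27 (limma, adjusted p = 0.018), a call lost without replicate 2 of Snf1. ADE2 differed by 0.48 ± 0.15 (limma, adjusted p = 0.068, or 0.012 with the block). HIS3 signals were under 1 on all 4 arrays and TRP1 signals were 12.9 to 20.8, both below the brightness filter and not tested.

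Cytosolic ribosomal protein genes rose together. Of 138 such genes 81 had a probe set annotated to that gene alone past the filter, since probe sets annotated to several genes were not assigned. Of these 65 rose and none fell, and 72 rose when adjusted over the list alone, at a median of 0.90, or 1.87-fold (camera, adjusted p = 3.1e-30; adjusted p = 0.198 with an estimated correlation). The median was 0.89 in pair 1 and 0.92 in pair 2. With plain _at probe sets alone 51 of these genes were tested and 41 rose. RPS22A rose by 1.40 ± 0.15, RPL13B by 1.25 ± 0.14, RPL24A by 1.23 ± 0.15 and RPS1A by 1.23 ± 0.15, the last on a probe set without a plain _at name. RPL24B, named after its values were seen, was at 2.60 ± 1.17 (limma, adjusted p = 0.16), since its Snf1 arrays read 504 and 7775. Rises numbered 19 without replicate 1 of Snf1 and 20 without replicate 2 of Snf1, where the lone Snf1 array is assumed to vary like the Snf1-I132G arrays. The array's ribosomal RNA control probe sets, which were not tested, had a median log2 difference of 0.78 over 10 probe sets, and its hybridization controls 0.23 over 9.

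Of 33 ribosome biogenesis genes 3 were higher, none when adjusted over the list alone, at a median of 0.48 (camera, adjusted p = 7.0e-06; adjusted p = 0.469 with an estimated correlation). The 3 were CBF5 at 0.70 ± 0.18, NHP2 at 0.69 ± 0.18 and NOP58 at 0.66 ± 0.15, and the other 3 NOP58 probe sets did not pass. GAR1 was at 0.79 ± 0.23 (limma, adjusted p = 0.054, or 7.4e-04 with the block). With the block 19 rose, with quantile normalization 6, with median centring 9 and with centring on hybridization controls 0. Rises numbered 0 without replicate 1 of Snf1, 0 without replicate 2 of Snf1-I132G, 1 without replicate 2 of Snf1 and 6 without replicate 1 of Snf1-I132G. Glycolysis and fermentation genes were higher in 4 of 16 cases and lower in 1, with the same counts adjusted over the list alone, at a median of 0.51 (camera, adjusted p = 5.3e-05; adjusted p = 0.424 with an estimated correlation). The phosphofructokinase genes PFK1 and PFK2 rose by 1.21 ± 0.20 and 1.20 ± 0.20, the pyruvate kinase gene CDC19 by 0.81 ± 0.20 and TDH1 by 0.66 ± 0.18, while PDC5 fell by 0.82 ± 0.22. With the block 14 of these genes rose. Their rises numbered 0 without replicate 2 of Snf1, 2 without replicate 1 of Snf1, 2 without replicate 1 of Snf1-I132G, 2 with centring on hybridization controls and 2 without the brightness filter, and PDC5 no longer passed with quantile normalization, with median centring, without that filter, without either Snf1 array or without replicate 2 of Snf1-I132G.

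**Figure D3:**
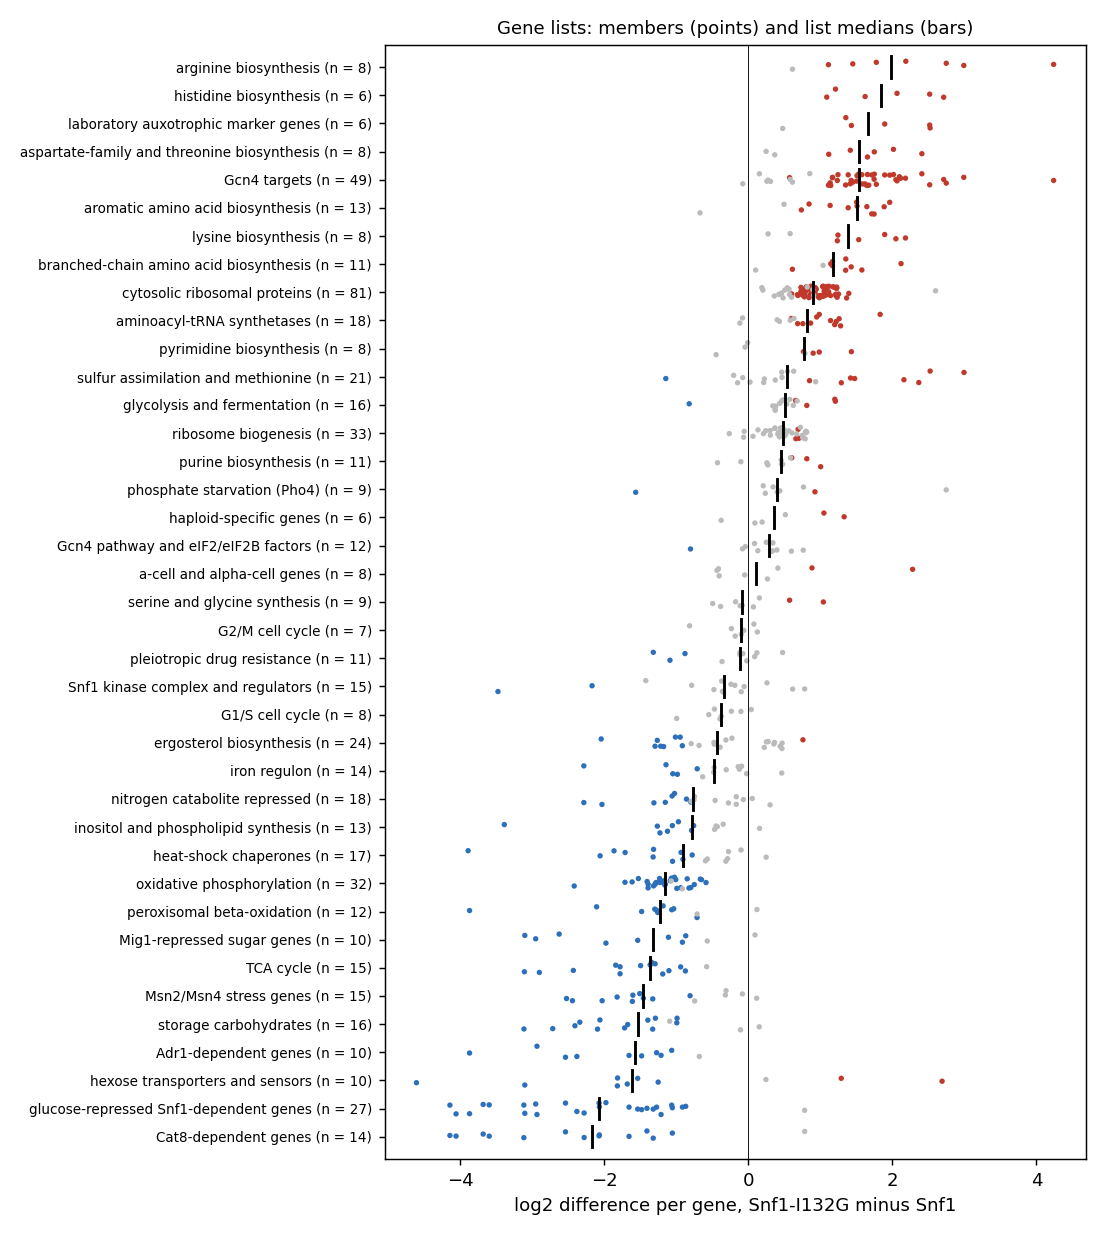
Log2 difference per gene, Snf1-I132G minus Snf1, for the 39 tested gene lists, ordered by list median; each point is a gene, red if higher, blue if lower and grey if not past the threshold, and black bars are list medians. Medians run from -2.17 for Cat8-dependent genes to 1.98 for arginine biosynthesis.

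Of the 40 lists 39 were tested, and 30 shifted in camera with its preset correlation of 0.01, 18 upward and 12 downward. Several lists share genes, so these 30 are not separate results. All 30 also shifted with the pair as a block, and the median of each had the same sign in both pairs. With the correlation estimated from the data no list passed (camera, lowest adjusted p = 0.198), and 6 did at an unadjusted p under 0.05. That test has 2 residual degrees of freedom here. Limma's fry, which asks whether the genes of a list move one way on balance, called 28, of which 24 were among those 30. The 6 that fry did not call were ribosome biogenesis (adjusted p = 0.324), the Gcn4 pathway (0.306), phosphate (0.229), glycolysis and fermentation (0.174), purine (0.148) and pyrimidine synthesis (0.052). The 4 that fry called and camera did not were the Snf1 complex and regulators (adjusted p = 0.0054), pleiotropic drug resistance (0.015), hexose transporters and sensors (0.016) and the iron regulon (0.034).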

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

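The signals below were looked at without a planned test, after the groups had been compared. Several kinds of control probe sets, outside the tested measurement, differed between the groups. Probe sets for ribosomal RNA among the array's controls were higher in Snf1-I132G by a median log2 difference of 0.778 over 10 probe sets, 0.989 in pair 1 and 0.515 in pair 2, and in 8 of them both Snf1-I132G arrays lay above both Snf1 arrays. Hybridization controls, bacterial and phage sequences added in fixed amounts, were higher by a median of 0.226 over 9 probe sets, 0.346 in pair 1 and 0.107 in pair 2. The URA3 control probe set was higher by 1.06, at 4431 ± 9.19 against 2122 ± 7.97 (SD, n = 2), in the direction of the tested URA3 probe set at 1.43 ± 0.14 (SE). The other 3 of the 4 control probe sets of this kind, for yeast genes, had lower means in Snf1-I132G. The one for RIP1 was at -1.42, with 670 ± 17.9 against 1817 ± 56.5, and the one for WBP1 at -0.49, with 765 ± 33.7 against 1088 ± 134, and the median over the 4, URA3 included, was -0.40.

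As signs of RNA integrity, the log2 ratio of the 3′ to the 5′ probe set differed between the groups by 0.04 for ACT1, 0.21 for SPT15 and -0.45 for SRB4.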

How the results depend on the processing

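Centring on hybridization controls and the limit to plain _at probe sets were chosen after seeing the data. No called list or named gene changed direction under any alternative tried. With the pair as a block 1354 probe sets were higher and 1984 lower. Apart from the genes given with their blocked values and further list members counted in the list totals, the block changed no call of a named gene or list. Centring on hybridization controls gave 2055 lower probe sets, 172 at least 2-fold higher and 793 at least 2-fold lower in both pairs, as it moves the zero point. Plain _at probe sets gave 464 higher, and 191 at least 2-fold higher in both pairs, with fewer probe sets tested. Leaving out each array in turn gave 325 to 664 higher and 451 to 1069 lower, with fewer arrays. With an estimated correlation 0 lists shifted, including the Gcn4 targets at 1.53 (camera, adjusted p = 0.198) and the glucose-repressed genes at -2.07 (camera, adjusted p = 0.198), in a test with 2 residual degrees of freedom. Within pair 2 alone the Gcn4 median was 1.62 and the glucose-repressed median -1.78, and the cause was not tested. The number of shifted lists was 28 to 31 under the other alternatives. Over named genes and alternatives, 2465 values counted as unchanged, 101 no longer passed and 53 newly passed. Of those no longer passing, 24 came without replicate 1 of Snf1 and 27 without replicate 2 of Snf1. Over lists and alternatives 654 counted as unchanged, 44 no longer passed, 30 of them with the estimated correlation, and 10 newly passed. Values within 1 pair alone, which have no test and so no side of the threshold, are among those counted. In 4 gene values and 32 list medians, a value that was not called changed sign or a median within 1 pair moved beyond its spread. Signals near the pseudocount limit what can be said of dim genes.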

Other observations

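The tests of short RNA carry-over, of array runs, of other amino acid pathway genes, of other splits of the arrays and of snoRNA length were chosen after the result was seen. Probe sets for tRNA genes were higher in Snf1-I132G. Of 83 tested 63 rose and none fell in limma, at a median log2 difference of 1.47, 1.26 in pair 1 and 1.52 in pair 2, with median signals of 365 against 113. Of the tRNA probe sets 2 have plain _at names, and with plain _at probe sets alone neither rose, at a median of 0.74. One of them, YNCG0028W, named after its values were seen, was at 1.16 ± 0.69 (limma, adjusted p = 0.26, or 0.012 with the pair as a block). Of 38 snoRNA probe sets 14 rose and none fell, at a median of 0.50, and centring on hybridization controls left 8 rises and leaving out the brightness filter 9. The snoRNA rises numbered 6 without replicate 1 of Snf1, 2 without replicate 2 of Snf1 and 8 without replicate 2 of Snf1-I132G. Longer snoRNAs, over 120 nucleotides, were at a median of 0.80 over 21 probe sets and shorter ones at 0.14 over 17. The difference was 0.66 (two-sided permutation test, p = 0.0051), in a test that takes probe sets as independent, which was not shown. Other non-coding classes also had medians above 0, at 0.95 over 5 probe sets for ribosomal RNA, of which 1 rose, and at 0.64 over 4 for snRNA, of which none passed, while the array's ribosomal RNA controls were at 0.78. Protein-coding genes were at a median of -0.16 over 5572 probe sets, with 466 higher and 1092 lower.

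Genes of mating were among the rises. MF(ALPHA)2, for the alpha-factor pheromone, rose from 2025 ± 910 to 9683 ± 3282 (SD, n = 2), by 2.28 ± 0.38 (limma, adjusted p = 0.011), and SAG1, for alpha-agglutinin, rose by 0.88 ± 0.17. The list of a-cell and alpha-cell genes had these 2 rises among 8 genes, also 2 adjusted over the list alone, and did not shift (camera, adjusted p = 0.19). As the list joins markers of both mating types, it could mask a shift limited to those of alpha cells. Its median of 0.11 turned to -0.12 with centring on hybridization controls, where 1 of its genes fell. SAG1 no longer passed with that centring, without replicate 1 of Snf1 or without replicate 2 of Snf1. STE3, for the a-factor receptor, was at 0.41 ± 0.15 (limma, adjusted p = 0.10, or 0.020 with the pair as a block). MFA2, for a-factor, was at -0.41 ± 0.18, and it did not pass. Of 6 haploid-specific genes SST2 and FUS3 rose, by 1.33 ± 0.16 and 1.05 ± 0.16, or 3 genes adjusted over the list alone, at a median of 0.35 (camera, adjusted p = 0.019; adjusted p = 0.303 with an estimated correlation). FUS3 was lost without replicate 1 of Snf1, and 1 haploid-specific gene fell with centring on hybridization controls. GPA1 was at 0.52 ± 0.15 (limma, adjusted p = 0.052, or 0.011 with the block) and RME1 at -0.38 ± 0.17 (0.16, or 0.031).

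Nitrogen catabolite genes were lower. Of 18 tested 8 fell, or 10 adjusted over the list alone, at a median of -0.77 (camera, adjusted p = 0.0089; adjusted p = 0.261 with an estimated correlation). CAR2, of arginine breakdown, was at -2.28 ± 0.26, the general permease gene GAP1 at -1.31 ± 0.17, GDH2 at -1.06 ± 0.19 and PUT2 at -1.02 ± 0.17. Falls numbered 5 with quantile normalization, 5 with median centring, 4 without replicate 1 of Snf1 and 2 without replicate 2 of Snf1. In the iron regulon 5 of 14 genes fell, or 6 adjusted over the list alone, at a median of -0.48, and the list did not shift (camera, adjusted p = 0.078). Siderophore transporter gene SIT1 was at -2.28 ± 0.27, CCC2 at -1.14 ± 0.17, FTR1 at -1.05 ± 0.27, TIS11 at -0.98 ± 0.17 and FRE3 at -0.71 ± 0.17. TIS11 had a signal of 27.7 in Snf1-I132G, so its size rests partly on the pseudocount. Iron falls numbered 3 with quantile normalization, with median centring, without the brightness filter and without replicate 1 of Snf1-I132G, 2 without replicate 1 of Snf1 and 1 without replicate 2 of Snf1, and with the block 1 iron gene rose.

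In the phosphate list VTC4 rose by 0.93 ± 0.17 and PHO89 fell by 1.56 ± 0.39 among 9 genes, with the same 2 adjusted over the list alone, at a median of 0.40 (camera, adjusted p = 0.018; adjusted p = 0.424 with an estimated correlation). That shift was lost without replicate 2 of Snf1 (camera, adjusted p = 0.12) and without replicate 2 of Snf1-I132G (0.062). VTC4 was lost without replicate 2 of Snf1, and phosphate rises numbered 3 with the block, 2 with median centring and 2 without replicate 1 of Snf1. PHO89 was lost with quantile normalization, with median centring, without the brightness filter, without replicate 1 of Snf1 and without either Snf1-I132G array. The phosphate transporter gene PHO84 was at 2.75 ± 0.82 with arrays far apart, 4105 ± 2217 against 770 ± 768 (limma, adjusted p = 0.058, or 0.0063 with the block). SPL2 was at 0.77 ± 0.34 and did not pass.

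Ergosterol genes did not shift as a list (camera, adjusted p = 0.48; median -0.43), with 8 of 24 lower and 1, ERG12 at 0.76 ± 0.16, higher, the same counts adjusted over the list alone. ERG28 was at -2.04 ± 0.28, HMG1 and HMG2, for HMG-CoA reductases, at -1.26 ± 0.22 and -1.17 ± 0.19, and ERG9 at -1.01 ± 0.17. With the block 13 fell and 4 rose, and with quantile normalization and with median centring 3 rose. Ergosterol falls numbered 2 without replicate 1 of Snf1 and 5 without replicate 2 of Snf1-I132G, and ERG12 did not pass when any 1 array was left out or with centring on hybridization controls. In pleiotropic drug resistance 3 of 11 genes fell, also 3 adjusted over the list alone, PDR10 at -1.32 ± 0.15, RSB1 at -1.09 ± 0.20 and PDR15 at -0.88 ± 0.15. That list did not shift (camera, adjusted p = 0.56; median -0.12, or 0.07 with median centring), and without replicate 1 of Snf1 1 of its genes fell. PDR16 was at 0.48 ± 0.15 (limma, adjusted p = 0.068, or 0.011 with the block).

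Cell cycle genes did not pass singly, in 8 tested G1/S genes (camera, adjusted p = 0.33; median -0.38) or 7 tested G2/M genes (camera, adjusted p = 0.94; median -0.10, or 0.04 with quantile normalization and 0.09 with median centring), and none did adjusted over the list alone. PCL1 was at -0.99 ± 0.32 (limma, adjusted p = 0.072, or 0.0095 with the block) and CDC5 at -0.81 ± 0.24 (0.053, or 0.0070). With centring on hybridization controls 2 G1/S genes and 1 G2/M gene fell, without replicate 1 of Snf1-I132G 1 of each list did, and with a pseudocount of 64, with a filter at the 50th percentile and with plain _at probe sets 1 G2/M gene did.

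The joint rise of ribosomal protein genes was set against bias with brightness and against array scaling. In 10000 lists of other genes matched on mean signal the typical median was -0.08 and the highest 0.31, so the list lay 0.985 above the typical one, which argues against brightness. Over quantile normalization, median centring and centring on hybridization controls, the lowest list median was 0.667, which argues against scaling as the whole cause. A candidate explanation that stays open is that ribosomal protein genes are higher when Snf1 is inhibited. This hypothesis was found on these arrays, which all had inhibitor and so cannot decide it. An effect of the I132G allele without inhibitor also stays open, as untested.

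The rise of tRNA-gene probe sets was set against brightness, shared family probes and carry-over of short RNA. Their median lay 1.64 above that of brightness-matched lists of other probe sets, whose highest median was 0.12. Of these sets 72 are family (_f_at) probe sets, and they lay 1.19 above 412 other family sets (permutation p = 1e-05, the smallest these draws can give). That difference argues against family design as the whole cause. Such probe sets do not tell the genes of a tRNA family apart, however, and neither plain _at probe set rose without the block. All 83 tRNA-gene sets lay 1.34 above 17 snoRNAs of at most 120 nucleotides (permutation p = 1e-05, the smallest these draws can give), which argues against a carry-over of all short RNA alike. Both permutations take probe sets as independent, which those of a tRNA family are not. Neither p-value can therefore be taken at its size, and only the differences of medians are used here. A difference in tRNA or its precursors with Snf1 inhibition may remain as a hypothesis, and a difference in RNA preparation or priming that reaches several kinds of non-coding RNA stays open, as ribosomal RNA, snRNA and longer snoRNAs also had medians above 0 and it was not tested.

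The rise of Gcn4 targets was set against array scaling, differences between runs and a general rise of amino acid pathway genes. The lowest list median over the 3 other scalings was 1.30, and the lower of the within-pair medians was 1.50. These values argue against scaling, and against a difference limited to 1 run, as the whole cause. Both pairs may hold the same RNA pools, so a difference between the pools would recur in both and was not tested. The 43 other amino acid pathway genes had a median of 0.61, with 19 rises and 1 fall. The 49 targets lay 0.921 higher (permutation p = 6e-05). That permutation takes genes as independent, which co-regulated genes are not, so its p-value cannot be taken at its size. By the difference of medians alone, the rise on these arrays was larger in the targets. Greater Gcn4 activity when Snf1 is inhibited is a candidate explanation and no more than a hypothesis, since the list was picked with knowledge of the study. An effect of the allele itself stays open, as untested.

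Of the 3 splits of the 4 arrays into 2 and 2, 1 gave at least as many called probe sets as the real one, namely the real one with 1921. The highest of the other splits gave 0, and 3 splits are too few for a share under 0.05. Each other split puts 1 array of each group on either side, so the difference between the groups adds to the spread within sides. A low count there could be foreseen, so this comparison cannot decide whether the calls arose at random.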
